A study of Homo sapiens with 12 samples.

How the data were processed

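Small RNA libraries of K562 cells, a human erythroleukemia line, were compared in 4 groups of 3 libraries: wild type and SAR1A knockout, each untreated or given hydroxyurea at 100 uM for 72 h. The groups are written WT, WT_HU, KO and KO_HU. Groups and replicate numbers were taken from the sample titles. Per the labels, miRNA was isolated with an miRNeasy micro kit. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels also do not say whether the knockout cells were a single clone or a pool.

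The deposited table holds estimated counts per mature miRNA and library, with no normalization. That unit was inferred from the values, because library totals were unequal and 281 of the 1092 miRNAs held at least 1 value that was not whole (tolerance 1e-06). Those 281 miRNAs held 69.1% of all counts. Per the submitters' processing notes, the software was Partek and the genome build hg38, with no version of Partek. The aligner, the miRNA annotation release, the rule for reads that match several miRNAs, adapter trimming and the use of strand are not given in the sources used here. Values were rounded to whole numbers before the count tests. The prefix for human was dropped from miRNA names.

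Some names shared reads. The values of miR-423-5p and miR-3184-3p, of miR-103a-3p and miR-103b, of miR-122-5p and miR-122b-3p, of miR-365a-3p and miR-365b-3p and of miR-374b-5p and miR-374c-3p were equal in every library, as were, at a mean below 100 counts, those of miR-129-1-3p and miR-129-2-3p and of miR-642a-3p and miR-642b-5p after rounding. Among miRNAs with a mean of at least 100 counts and a value that was not whole, those of let-7a-5p and let-7c-5p, of miR-107 with miR-103a-3p and of miR-378c and miR-378d differed by less than 0.25 log2 units in every library. The paired hairpins of miR-486, and those of miR-24-3p with miR-3074-5p and of miR-7-5p with miR-3529-3p, lie on opposite strands of the same place. Such names are counted separately below, and their values cannot be assigned to 1 locus. With equal names taken as 1, the 579 tested names were 572 measurements, of which 138 rather than 140 passed in knockout untreated. Hairpin names and positions come from RefSeq genes. Their strand, host genes and the exon or intron they lie in come from GENCODE release 29 on GRCh38, which is the assembly that hg38 names. Positions and hosts are given for miRNAs with 1 hairpin (991 of 1092, with 1088 matched to any). Whether the authors used the same annotation is not given in the sources used here.

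The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the low count filter of filterByExpr by group. All 12 libraries entered 1 fit of 4 group means (8 residual degrees of freedom) with no replicate block, and 5 contrasts were taken: hydroxyurea in each genotype, knockout against wild type in each treatment, and the difference of the responses. The filter kept 579 miRNAs, which held 99.9% of the counts, and left out 513. Benjamini-Hochberg adjustment ran over the 579 within each contrast, with a threshold of 0.05. An adjusted p below is that of this test unless another tool is named. CPM are counts per 1e6 of the TMM-scaled totals. Errors of log2 fold changes are standard errors (SE) of the fit, and errors of CPM and shares are standard deviations (SD) over 3 libraries. A fold is 2 raised to the fitted log2 fold change. Ratios of pooled counts carry exact 95% intervals. Those intervals cover counting error only, since the reads carry no stated molecular identifiers.

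Before the data were examined, 26 miRNA lists were fixed, and each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 26 lists within a comparison. No list call held with an estimated correlation in any of the 5 comparisons. List counts were made over all 579 miRNAs and also adjusted over the list alone. Where the second count is not given it equals the first. Lists overlap: miR-486, miR-144, miR-210 and miR-16 belong to both the erythroid and the fetal hemoglobin-linked lists, and miR-181a to 3 lists. Lists of other tissues were included as markers of cells other than K562.

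Single values per library were compared with exact two-sided permutation tests over 20 assignments, which for 3 against 3 cannot give a p below 0.1. On simulated counts for the 579 miRNAs (5 runs with 200 changed miRNAs each), the test recovered 27.4% of 2-fold, 79.5% of 4-fold and 93.3% of 8-fold changes for knockout against wild type, untreated. For hydroxyurea in wild type it recovered 26.5%, 78.0% and 89.5%, and for hydroxyurea in knockout 23.7%, 78.9% and 90.3%. For knockout against wild type under hydroxyurea the shares were 23.2%, 81.1% and 93.9%. For the difference of the responses they were 7.83%, 46.9% and 75.1%. These shares hold for 200 changed miRNAs and for counts drawn without replicate effects. Where few miRNAs change, the adjusted threshold is harder to pass. The shares may thus be too high for the hydroxyurea contrasts and the difference of the responses, where few miRNAs passed.

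The replicate numbers paired the samples. Over 406 miRNAs, the deviations from the group means correlated with r between 0.455 and 0.765 in all 18 pairs of libraries with the same number, and between -0.639 and 0.138 in pairs with different numbers. All 12 libraries were closest to a library of their own number, and library names in the labels share a code within a number. Libraries were thus not exchangeable, so the 10% share of miRNAs whose 3 against 3 values do not overlap, which holds for exchangeable libraries, is not the share expected here without an effect. No 2 libraries of the same group agreed within sampling noise, the lowest chi-square per degree of freedom between replicates being 64.6.

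The rule for named miRNAs was fixed before the data were examined. It took, for each direction of the first 3 contrasts, up to 10 miRNAs past the threshold with the largest fold change, at least 10 CPM in 1 of the 2 groups and the same direction in all 3 same-numbered pairs. It took 5 for knockout under hydroxyurea and, without the condition on pairs, for the difference of the responses, and filled each direction up to 5 with the next smallest p. For each list it took up to 4 members past the threshold and, where none passed, the 2 most abundant members. This last part was followed by name for knockout against wild type, untreated. In the hydroxyurea contrasts and the difference of the responses, where nearly every list had no member past the threshold, those members were named for some lists only and the whole set is given as a range, as it is for 4 lists in knockout under hydroxyurea. That departure was made after the values were seen, as was the naming of miR-584-5p in every contrast, miR-144-5p, miR-451a, miR-9-5p, miR-199b-5p, miR-371a-5p, the 3p arms of miR-129 with hydroxyurea, miR-106a-5p, miR-20a-5p, miR-18a-5p and miR-664a-3p in knockout, and the miRNAs of the arm comparison and of the sterol-responsive hosts.

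Alternatives fixed before the data were examined were RLE, upper quartile and total-count scaling, no filter and a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, removal of entries that overlap structural RNA, removal of the 3 most abundant miRNAs, a fold change minimum of 1 log2 unit, a fit of the 2 compared groups alone, and leaving out each library. Adjustment for hairpin GC content, alone or with the block, and thinning of every library to 1362273 counts were added after the data were seen. Other computations used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.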

Results

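The series asked how miRNA levels differ between K562 cells with and without SAR1A, a small GTPase of the COPII coat on vesicles that leave the endoplasmic reticulum, and how hydroxyurea changes them. Hydroxyurea inhibits ribonucleotide reductase and is given in sickle cell disease to raise fetal hemoglobin, and the title of the series calls SAR1A inducible by the drug. Counts of 1092 mature miRNAs were available in 12 libraries, 3 per group. Total counts were 2867293, 3304033 and 3002570 in WT, 1674870, 4417456 and 3017688 in WT_HU, 2022678, 1801564 and 1748137 in KO, and 1712263, 1362273 and 1662799 in KO_HU. The mRNA of SAR1A is not part of miRNA counts, so the loss of the targeted gene could not be checked from these data. The most abundant miRNAs were miR-92a-3p, miR-148a-3p, miR-21-5p, miR-378a-3p and miR-146b-5p.

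The libraries separated first by genotype. The first principal component of log2 CPM held 47.9% of the variance and parted knockout from wild type, while the second held 18.8% and set replicate 2 of each group apart from replicates 1 and 3. The most abundant miRNAs took a smaller share in knockout, with the top 10 holding 62.8% ± 2.68 (SD, n = 3) in KO against 68.2% ± 1.59 in WT (exact permutation p = 0.1, the smallest possible). Entries that overlap structural RNAs such as tRNA, snRNA and snoRNA held 1.89% ± 0.232 of counts in KO and 1.89% ± 0.151 in KO_HU, against 0.0690% ± 0.0280 in WT and 0.0567% ± 0.0297 in WT_HU (exact permutation p = 0.1 in both treatments). miR-1246 alone held 1.57% ± 0.0881 in KO. Total counts and the number of miRNAs with a count (942 ± 12.5 in KO, 974 ± 13 in WT) were also lower in KO (exact permutation p = 0.1 for each). Between KO_HU and WT_HU the exact permutation p was 0.2 for total counts, 0.3 for miRNAs with a count and 0.1 for the share of the top 10. Between WT_HU and WT it was 1, 1, 0.2 and, for structural RNA, 0.5, and between KO_HU and KO 0.1, 0.7, 0.3 and 1.

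Untreated knockout cells differed from wild type in a large part of the miRNA profile, and the highest fold change was that of miR-1246, whose sequence also occurs in the U2 small nuclear RNA. It was 15512 ± 1895 CPM in KO and 17.7 ± 6.94 CPM in WT (SD, n = 3), a log2 fold change of 9.77 ± 0.37 (SE), or 872-fold (edgeR adjusted p = 1.08e-07). Members of the oncogenic miR-17-92 family fell, among them miR-92a-3p, the most abundant miRNA of these cells (-1.0 ± 0.20, adjusted p = 0.00480). miR-33b-3p and miR-1908-5p, which lie in the sterol and fatty acid genes SREBF1 and FADS1, fell to 6.60 ± 1.19 from 46.4 ± 1.61 CPM and to 9.64 ± 0.744 from 117 ± 29 CPM. The p53-responsive miR-192-5p rose from 2808 ± 380.0 to 9955 ± 1632 CPM (1.83 ± 0.21, adjusted p = 1.31e-04).

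Of 579 miRNAs, 140 passed the threshold, 70 higher and 70 lower in knockout, and 130 of them changed at least 2-fold (64 higher, 66 lower). The groups did not overlap for 233 miRNAs (40.2%, where exchangeable libraries without an effect would give 10%). With the replicate block 218 miRNAs passed (119 higher, 99 lower), including all 140. The count was 90 without KO replicate 3 (40 higher, 50 lower) and 100 without WT replicate 1 (29 higher, 71 lower), and a fit of the 2 groups alone gave 46 higher and 74 lower, so the even split did not hold in each. Scaling to library totals alone gave 95 higher and 63 lower, since it moved the median log2 fold change of all miRNAs by 0.14, from 0.14 to 0.28.

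Besides miR-1246, the miRNAs named for their rise were miR-1290, miR-3609 (5.54 ± 0.71), miR-12136 (5.04 ± 0.51), miR-3681-5p (4.65 ± 0.50), miR-10395-3p (4.14 ± 0.40), miR-3159 (4.01 ± 0.56), miR-4485-3p (3.72 ± 0.84), miR-5701 (3.22 ± 0.69) and miR-4791 (3.12 ± 0.45), each higher in 3 of 3 same-numbered pairs. miR-1290 had 431 counts in KO and 2 in WT, a depth-corrected ratio of 316 (exact 95% interval 86.9 to 2616). miR-12136 rose from 84.4 ± 37.8 to 2779 ± 1604 CPM (adjusted p = 1.31e-04). The call of miR-4485-3p was lost without WT replicate 1 (adjusted p = 0.0516). In the annotation, the hairpin of miR-1246 (chromosome 2, 176600980 to 176601052) has no host gene, miR-3609 lies in an intron of TRRAP (chromosome 7, 98881650 to 98881729) and miR-4485 in an exon of MTRNR2L8 (chromosome 11, 10508270 to 10508326).

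The miRNAs named for their decrease were miR-1260a, miR-1908-5p (-3.60 ± 0.33, adjusted p = 6.28e-05), miR-877-3p (-3.47 ± 0.64), miR-1268b (-3.31 ± 0.52), miR-4695-3p (-3.18 ± 0.88), miR-1260b (-2.90 ± 0.51), miR-33b-3p (-2.80 ± 0.30, adjusted p = 8.19e-05), miR-3940-3p (-2.79 ± 0.58), miR-210-5p (-2.76 ± 0.79) and miR-92a-1-5p (-2.74 ± 0.51), each lower in 3 of 3 pairs. miR-1260a had 3 counts in KO and 101 in WT, a depth-corrected ratio of 23 (exact 95% interval 7.64 to 113). miR-1908 lies in an exon of FADS1, a fatty acid desaturase (chromosome 11, 61815161 to 61815240), and miR-33b in an intron of SREBF1, a transcription factor of lipid synthesis (chromosome 17, 17813836 to 17813931). The call of miR-4695-3p was lost without KO replicate 3 (adjusted p = 0.0549). That of miR-210-5p was lost without WT replicate 2 (adjusted p = 0.0561), KO replicate 1 (0.0694) or KO replicate 3 (0.0725).

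**Figure D1:**
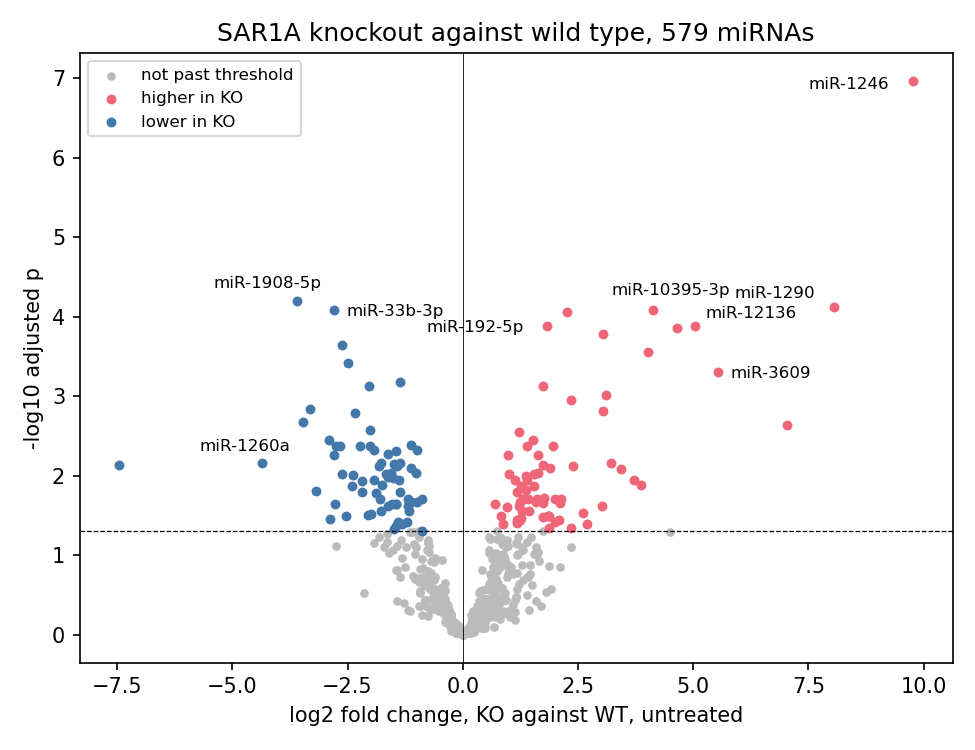
Log2 fold change of KO against WT, untreated, against -log10 of the edgeR adjusted p for 579 miRNAs, with 3 libraries per group. Each point is a miRNA and the dashed line is an adjusted p of 0.05; 70 miRNAs lay above it as higher and 70 as lower, with miR-1246 at 9.77.

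Of the 26 lists, 4 passed the set test and are described first. In the miR-17-92 cluster and its paralogs, which promote proliferation, 7 of 22 members were lower and none higher (median -0.96, camera adjusted p = 0.00229, adjusted p = 0.460 with an estimated correlation). They were miR-92a-1-5p, miR-92a-3p, miR-17-5p (-1.45 ± 0.29), miR-25-5p (-1.50 ± 0.32), miR-106a-5p, miR-20a-5p and miR-18a-5p. Of 27 members of the imprinted 14q32 cluster only miR-370-3p was lower past the threshold (-1.93 ± 0.46), while the list median was -0.93 (camera adjusted p = 0.00229, adjusted p = 0.465 with an estimated correlation, and 0.0632 over members of at least 10 CPM). Mirtrons, which are spliced from short introns without Drosha, were lower for 4 of 5 members, and for 5 of 5 adjusted over the list alone: miR-877-3p, miR-1226-3p (-2.01 ± 0.35), miR-877-5p (-1.12 ± 0.25) and miR-1227-3p (-2.18 ± 0.55), with a camera adjusted p = 0.00229 and an adjusted p = 0.399 with an estimated correlation. Entries that overlap structural RNA went both ways, with 5 of 9 higher (miR-1246, miR-12136, miR-664a-5p, miR-4485-3p and miR-664a-3p) and 2 lower (miR-1260a and miR-1260b), and a camera adjusted p = 0.00307 (adjusted p = 0.460 with an estimated correlation). The medians of these 4 lists kept their sign under each of the 4 scalings.

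The other lists did not pass the set test (camera adjusted p between 0.0997 and 0.899). Among miRNAs of erythroid maturation, 1 of 11 was higher and 2 lower, and adjusted over the list alone 3 were higher and 2 lower. miR-486-3p rose (0.98 ± 0.20; adjusted p = 0.0529 without WT replicate 1) and miR-210-5p and miR-16-1-3p (-2.07 ± 0.62) fell, while the erythroid miR-451a (0.58 ± 0.21, adjusted p = 0.0618) and miR-486-5p (0.57 ± 0.20, adjusted p = 0.0588) did not pass, but did with the replicate block (adjusted p = 0.0261 and 0.0321). Of 31 fetal hemoglobin-linked miRNAs, 2 were higher and 6 lower, among them miR-221-5p (-1.78 ± 0.38), miR-222-3p (-1.11 ± 0.31) and miR-27a-3p (0.71 ± 0.20). Of the 11 DNA damage and p53-linked miRNAs, 3 were higher and none lower: miR-192-5p, miR-194-5p (1.23 ± 0.39) and miR-215-5p (2.70 ± 0.82). The medians of the erythroid, fetal hemoglobin-linked, let-7, miR-15/16 and miR-183 lists changed sign between scalings.

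In the hematopoietic progenitor list, 3 of 9 were lower (miR-223-5p at -1.92 ± 0.37, miR-221-5p and miR-222-3p), and 5 adjusted over the list alone. Of 9 megakaryocytic miRNAs 2 were lower, miR-146b-3p (-2.04 ± 0.30) and miR-126-5p (-1.35 ± 0.29), and 3 adjusted over the list alone. In the myeloid list 1 of 8 was higher (miR-142-5p, 0.96 ± 0.28) and 2 lower (miR-223-5p and miR-21-3p, -1.88 ± 0.48), with 3 lower adjusted over the list alone. Of 9 lymphoid miRNAs 3 were higher: miR-181b-5p (1.62 ± 0.33), miR-181a-5p (1.73 ± 0.52) and miR-142-5p. The miR-181 family had 2 of 5 higher, and 3 adjusted over the list alone. Among miR-23/27/24 miRNAs 1 of 9 was higher and 3 lower (miR-23b-5p, -2.65 ± 0.54, miR-27b-5p, -1.63 ± 0.38, and miR-27a-5p, -1.45 ± 0.47), with 2 higher adjusted over the list alone. In the miR-15/16 family 1 of 12 was higher (miR-503-5p, 1.13 ± 0.27) and 2 lower (miR-424-3p, -1.51 ± 0.36, and miR-16-1-3p).

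Single members passed in further lists. They were let-7e-3p (-1.62 ± 0.47) of 13 in the let-7 family, which did not pass adjusted over the list alone, miR-26b-3p (-1.41 ± 0.45) of 4 in the miR-26 family, miR-183-3p (-1.16 ± 0.34) of 5 in the miR-183 cluster, miR-516b-5p (1.60 ± 0.44) of 9 in the 19q13 cluster, and miR-29a-3p (1.29 ± 0.38) of 4 in the miR-29 family, where 2 passed adjusted over the list alone. Of 13 miRNAs linked to the unfolded protein response, 2 were higher (miR-204-5p, 1.44 ± 0.43, and miR-181a-5p) and 1 lower (miR-424-3p). Of 14 markers of muscle, liver and neural tissue, 3 were higher, all of them arms of miR-129 (miR-129-5p, 2.35 ± 0.36, and miR-129-1-3p and miR-129-2-3p, which held equal values, 1.86 ± 0.58). Those 3 names are 2 distinct measurements, of 13. No member passed in the miR-30 (11), HOX-linked (14), epithelial (9), stromal (8) or pluripotency (3) lists. Their 2 most abundant members were miR-30d-5p (-0.45) and miR-30b-5p (0.30), miR-10a-5p (-0.42) and miR-99b-5p (-0.25), miR-200c-3p (0.14) and miR-200b-3p (0.11), miR-143-3p (0.75) and miR-145-5p (-0.33), and miR-372-3p (-0.29) and miR-373-3p (-0.37).

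Of the 69 miRNAs named for this comparison that passed, 28 lost the call when some library was left out, and those not given elsewhere follow. Without KO replicate 1, these with their adjusted p were miR-1227-3p (0.0577), miR-16-1-3p (0.107), miR-181a-5p (0.0689), miR-18a-5p (0.109), miR-194-5p (0.124), miR-21-3p (0.0565), miR-215-5p (0.109), miR-27a-3p (0.0646), miR-27a-5p (0.130) and miR-29a-3p (0.129). Without KO replicate 2, these were let-7e-3p (0.0638), miR-1227-3p (0.0510), miR-129-1-3p (0.0676), miR-129-2-3p (0.0676), miR-142-5p (0.0521), miR-181a-5p (0.0676), miR-183-3p (0.0527), miR-194-5p (0.0831), miR-215-5p (0.0818), miR-222-3p (0.0611), miR-26b-3p (0.109), miR-27a-5p (0.0525), miR-516b-5p (0.0576) and miR-664a-3p (0.0527). Without KO replicate 3, these were let-7e-3p (0.0671), miR-129-1-3p (0.132), miR-129-2-3p (0.132), miR-16-1-3p (0.0773), miR-181a-5p (0.0983), miR-183-3p (0.0651), miR-18a-5p (0.0716), miR-204-5p (0.134), miR-21-3p (0.0524), miR-215-5p (0.0647), miR-222-3p (0.0646), miR-26b-3p (0.0767), miR-27a-3p (0.0668), miR-27a-5p (0.0715), miR-29a-3p (0.0671), miR-503-5p (0.0565), miR-516b-5p (0.0771) and miR-664a-3p (0.0588). Without WT replicate 1, these were let-7e-3p (0.0517), miR-129-1-3p (0.114), miR-129-2-3p (0.114), miR-142-5p (0.147), miR-16-1-3p (0.0514), miR-181a-5p (0.0960), miR-18a-5p (0.0743), miR-194-5p (0.0858), miR-204-5p (0.144), miR-215-5p (0.0514), miR-27a-3p (0.108), miR-503-5p (0.0743), miR-516b-5p (0.0909) and miR-664a-3p (0.0568). Without WT replicate 2, these were miR-129-1-3p (0.0962), miR-129-2-3p (0.0962), miR-181a-5p (0.0826), miR-194-5p (0.126), miR-204-5p (0.0930), miR-215-5p (0.126), miR-222-3p (0.0597), miR-26b-3p (0.0958), miR-27a-3p (0.0636), miR-27a-5p (0.101), miR-29a-3p (0.116) and miR-516b-5p (0.0629). Without WT replicate 3, these were miR-16-1-3p (0.0917), miR-194-5p (0.0957), miR-215-5p (0.139), miR-26b-3p (0.0678), miR-27a-5p (0.0799) and miR-29a-3p (0.101). In other settings 15 of the 69 lost the call, miR-584-5p among them. With upper quartile factors, the call lost (with its adjusted p) was that of miR-27a-3p (0.0554). With library totals alone, it was miR-26b-3p (0.0854). With no low count filter, these were miR-129-1-3p (0.0540), miR-129-2-3p (0.0540), miR-1307-5p (0.0503), miR-181a-5p (0.0540), miR-194-5p (0.0660), miR-204-5p (0.0648), miR-26b-3p (0.0575), miR-27a-3p (0.0768) and miR-29a-3p (0.0600). With structural RNA entries removed, these were miR-194-5p (0.0540) and miR-215-5p (0.0506). With the 3 most abundant miRNAs removed, it was miR-181a-5p (0.0518). With GC adjustment alone, these were miR-215-5p (0.0816), miR-27a-5p (0.0671), miR-29a-3p (0.192) and miR-664a-3p (0.0816). With thinned libraries, these were miR-129-1-3p (0.198), miR-129-2-3p (0.101), miR-16-1-3p (0.0618), miR-204-5p (0.114) and miR-215-5p (0.0530). With only the 2 groups compared, these were miR-129-1-3p (0.0719), miR-129-2-3p (0.0719), miR-1307-5p (0.0525), miR-181a-5p (0.0646), miR-194-5p (0.0604), miR-204-5p (0.0623), miR-26b-3p (0.0562), miR-27a-3p (0.116), miR-29a-3p (0.0663), miR-516b-5p (0.0623) and miR-664a-3p (0.0604).

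Under hydroxyurea the knockout again differed widely from wild type, led by miR-1246 (12424 ± 2741 CPM in KO_HU against 53 ± 24.6 in WT_HU, SD, n = 3; log2 fold change 7.86 ± 0.36, edgeR adjusted p = 5.54e-07). miR-1908-5p of FADS1 fell (-3.95 ± 0.33, adjusted p = 2.48e-05). The abundant erythroid miR-486-3p (1.03 ± 0.20) and miR-486-5p (0.78 ± 0.20) rose, and miR-221-5p (-2.54 ± 0.38) and miR-222-3p (-1.41 ± 0.31) fell. In all, 58 miRNAs passed as higher and 67 as lower, of which 110 changed at least 2-fold. The groups did not overlap for 218 (37.7%, against 10% for exchangeable libraries). With the replicate block 203 passed (98 higher, 105 lower), including all of these. Without WT_HU replicate 2 the count was 85 (37 higher, 48 lower), without KO_HU replicate 3 it was 93 (52 higher, 41 lower), and a fit of the 2 groups alone gave 45 higher and 44 lower. The balance of directions also depended on scaling: 46.4% of calls were higher with TMM, 35.6% with upper quartile factors (52 higher, 94 lower) and 59.4% with library totals (76 higher, 52 lower), which moved the median log2 fold change of all miRNAs by -0.16 and 0.27.

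The other named increases were miR-1290 (6.62 ± 0.83), miR-12136 (5.40 ± 0.51), miR-3609 (5.36 ± 0.71) and miR-10395-3p (4.05 ± 0.41), and the other decreases miR-1268b (-3.59 ± 0.57), miR-652-5p (-3.30 ± 0.60), miR-135b-3p (-2.91 ± 0.45) and miR-1260b (-2.86 ± 0.52). Mirtrons were lower for 4 of 5 members (miR-877-3p, -3.66 ± 0.75, miR-1227-3p, miR-1226-3p, -1.90 ± 0.36, and miR-877-5p, -0.90 ± 0.25; 5 adjusted over the list alone; camera adjusted p = 0.00726, adjusted p = 0.454 with an estimated correlation). Entries overlapping structural RNA had 3 of 9 higher (miR-1246, miR-12136 and miR-664a-3p, 1.41 ± 0.43) and 2 lower (miR-1260a and miR-1260b; 4 higher adjusted over the list alone; camera adjusted p = 0.00726, adjusted p = 0.710 with an estimated correlation). No other list passed the set test (camera adjusted p between 0.280 and 0.981). The ratio of pooled counts, wild type over knockout, was 15.9 for miR-1227-3p (2 counts in KO_HU, 49 in WT_HU; exact 95% interval 4.17 to 135), 14.6 for miR-1260a (2 and 45; 3.81 to 124) and 49.3 for miR-222-5p (1 and 76; 8.58 to 1971).

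Among erythroid miRNAs under hydroxyurea, 3 of 11 were higher (miR-486-3p, miR-486-5p and miR-16-5p, 0.99 ± 0.30) and 1 lower (miR-144-5p, -1.57 ± 0.43), with 2 lower adjusted over the list alone. Of 31 fetal hemoglobin-linked miRNAs 4 were higher and 6 lower (7 lower adjusted over the list alone). The miR-17-92 list had 4 of 22 lower: miR-92a-3p (-0.91 ± 0.20), miR-92a-1-5p (-2.06 ± 0.51), miR-17-5p (-1.14 ± 0.29) and miR-25-5p (-1.26 ± 0.32). In the p53-linked list miR-192-5p (1.16 ± 0.21) and miR-34a-5p (1.87 ± 0.61) were higher and miR-145-5p (-1.15 ± 0.35) lower, of 11. In the progenitor list 3 of 9 were lower (miR-221-5p, miR-222-3p and miR-222-5p), and 5 adjusted over the list alone. Among miR-23/27/24 miRNAs 3 of 9 were lower (miR-23b-5p, -2.73 ± 0.53, miR-27b-5p, -1.65 ± 0.38, and miR-27a-5p, -1.74 ± 0.47). In the let-7 family 2 of 13 were lower (let-7e-3p, -2.54 ± 0.49, and let-7a-3p, -1.31 ± 0.43), and 1 adjusted over the list alone.

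Lower members under hydroxyurea were also found in the stromal (2 of 8; miR-199b-5p, -1.19 ± 0.36, and miR-145-5p), unfolded protein response (2 of 13; miR-424-3p, -1.51 ± 0.36, and miR-30d-5p, -0.82 ± 0.20), 14q32 (2 of 27; miR-323b-3p, -2.29 ± 0.58, and miR-543, -2.72 ± 0.76), miR-30 (1 of 11; miR-30d-5p), miR-26 (1 of 4; miR-26b-3p, -1.62 ± 0.47) and miR-183 lists (1 of 5; miR-183-3p, -1.23 ± 0.35; 2 adjusted over the list alone). Higher members were found in the lymphoid (2 of 9, and 3 adjusted over the list alone; miR-181b-5p, 1.17 ± 0.33, and miR-142-5p, 0.91 ± 0.28), miR-29 (1 of 4; miR-29a-3p, 1.27 ± 0.38), miR-181 (1 of 5, and 2 adjusted over the list alone), 19q13 (1 of 9; miR-516b-5p, 1.48 ± 0.43) and myeloid lists (1 of 8, and 0 adjusted over the list alone). In the miR-15/16 family miR-503-5p, 1.18 ± 0.27, and miR-16-5p were higher and miR-424-3p lower, of 12, with 2 lower adjusted over the list alone. Of 9 megakaryocytic miRNAs miR-34a-5p was higher and miR-146b-3p, -2.26 ± 0.30, and miR-126-5p, -0.96 ± 0.29, were lower, with 4 lower adjusted over the list alone. In the HOX-linked, epithelial, tissue marker and pluripotency lists no member passed, although 3 of 3 pluripotency miRNAs were lower adjusted over the list alone, and their 8 most abundant members lay between -1.31 and 1.16 (lowest adjusted p = 0.0720). The medians of 8 lists changed sign between scalings.

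Of the 50 miRNAs named for this comparison that passed, 26 lost the call when some library was left out. Without KO_HU replicate 1, these with their adjusted p were miR-126-5p (0.0891), miR-1260a (0.0675), miR-144-5p (0.0730), miR-17-5p (0.0501), miR-181b-5p (0.0892), miR-183-3p (0.0900), miR-199b-5p (0.0916), miR-222-5p (0.0531), miR-26b-3p (0.0957), miR-27a-5p (0.0615), miR-29a-3p (0.0916), miR-34a-5p (0.25), miR-486-5p (0.0569) and miR-877-5p (0.0552). Without KO_HU replicate 2, these were let-7a-3p (0.150), miR-1260a (0.0728), miR-142-5p (0.0515), miR-145-5p (0.0915), miR-16-5p (0.0717), miR-222-5p (0.0655), miR-25-5p (0.0603), miR-26b-3p (0.0918), miR-516b-5p (0.0778), miR-664a-3p (0.104) and miR-92a-1-5p (0.0616). Without KO_HU replicate 3, these were let-7a-3p (0.245), miR-126-5p (0.115), miR-1260a (0.0785), miR-142-5p (0.0594), miR-144-5p (0.0980), miR-145-5p (0.191), miR-17-5p (0.0591), miR-183-3p (0.0932), miR-199b-5p (0.154), miR-222-5p (0.0944), miR-25-5p (0.0902), miR-27a-5p (0.0669), miR-29a-3p (0.0796), miR-30d-5p (0.0765), miR-323b-3p (0.0545), miR-34a-5p (0.0669), miR-424-3p (0.0598), miR-516b-5p (0.0522), miR-543 (0.0796), miR-664a-3p (0.0642), miR-877-5p (0.112) and miR-92a-1-5p (0.102). Without WT_HU replicate 1, these were let-7a-3p (0.156), miR-145-5p (0.0772), miR-16-5p (0.0713), miR-25-5p (0.0578), miR-26b-3p (0.0817), miR-34a-5p (0.0828), miR-486-5p (0.0509), miR-664a-3p (0.122) and miR-92a-1-5p (0.0881). Without WT_HU replicate 2, these were let-7a-3p (0.137), miR-142-5p (0.0784), miR-144-5p (0.0543), miR-145-5p (0.0845), miR-16-5p (0.0918), miR-181b-5p (0.0918), miR-183-3p (0.0563), miR-199b-5p (0.144), miR-222-5p (0.0556), miR-27a-5p (0.0555), miR-29a-3p (0.121), miR-30d-5p (0.0543), miR-323b-3p (0.0581), miR-34a-5p (0.162), miR-486-5p (0.0820), miR-516b-5p (0.0949), miR-543 (0.0556), miR-664a-3p (0.134) and miR-877-5p (0.0561). Without WT_HU replicate 3, these were miR-126-5p (0.0623), miR-1260a (0.124), miR-142-5p (0.0530), miR-181b-5p (0.0814), miR-199b-5p (0.0545), miR-222-5p (0.0624), miR-26b-3p (0.0716), miR-27a-5p (0.0624), miR-29a-3p (0.0859), miR-34a-5p (0.0831), miR-516b-5p (0.0791) and miR-877-5p (0.0545). In other settings 19 of the 50 lost the call. With RLE factors, the call lost (with its adjusted p) was that of let-7a-3p (0.0634). With upper quartile factors, these were miR-142-5p (0.0516) and miR-34a-5p (0.0523). With library totals alone, these were let-7a-3p (0.157), miR-126-5p (0.119), miR-145-5p (0.128), miR-183-3p (0.0815), miR-199b-5p (0.104), miR-25-5p (0.0841), miR-26b-3p (0.0807), miR-30d-5p (0.0513) and miR-877-5p (0.0737). With no low count filter, these were let-7a-3p (0.0845), miR-145-5p (0.0532), miR-34a-5p (0.0669) and miR-664a-3p (0.0603). With the stricter filter, it was let-7a-3p (0.0564). With structural RNA entries removed, these were let-7a-3p (0.107) and miR-145-5p (0.0682). With GC adjustment alone, these were let-7a-3p (0.0526), miR-126-5p (0.0682), miR-199b-5p (0.0745), miR-27a-5p (0.0526), miR-29a-3p (0.153), miR-664a-3p (0.137) and miR-877-5p (0.0937). With thinned libraries, these were let-7a-3p (0.0861), miR-145-5p (0.0569), miR-34a-5p (0.0861) and miR-516b-5p (0.0634). With only the 2 groups compared, these were let-7a-3p (0.180), miR-145-5p (0.0666), miR-181b-5p (0.0622), miR-199b-5p (0.0727), miR-25-5p (0.0769), miR-26b-3p (0.0502), miR-30d-5p (0.0513), miR-877-5p (0.0757) and miR-92a-1-5p (0.0787). With limma-voom, these were miR-1260a (0.0518), miR-222-5p (0.0825) and miR-34a-5p (0.0757).

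The knockout effect was largely shared between the treatments. Fold changes correlated across the 579 miRNAs (Pearson r = 0.863, Spearman rho = 0.821), which are not independent replicates, and 82.2% had the same sign. Both lists of calls shared 98 miRNAs, 46 higher and 51 lower in both, where independent lists would share 7.01 and 8.10. The 2 comparisons have no library in common. One miRNA passed in opposite directions, miR-584-5p, at 0.86 ± 0.28 untreated and -1.66 ± 0.28 under hydroxyurea. Its call in untreated cells was lost when each of the 6 libraries compared was left out in turn, with adjusted p from 0.0942 without KO replicate 2 to 0.172 without WT replicate 1, and in 8 of the other settings, with adjusted p up to 0.134 after thinning.

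**Figure D2:**
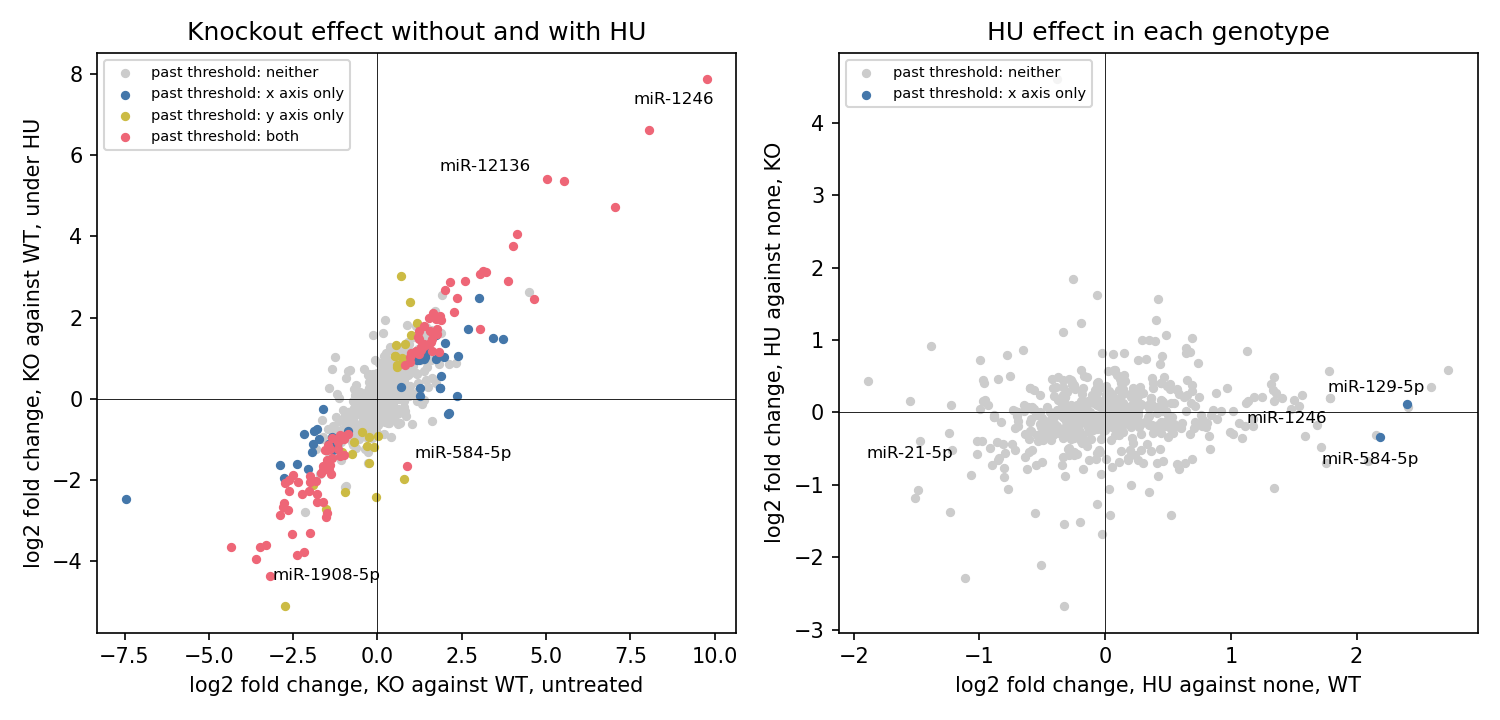
Left, log2 fold change of KO against WT without hydroxyurea (x) and with it (y); right, log2 fold change with hydroxyurea in WT (x) and in KO (y), for 579 miRNAs. Points are coloured by which comparison passed an edgeR adjusted p of 0.05. The knockout effects lie along a diagonal (r = 0.863), the hydroxyurea effects do not (r = 0.141). The hydroxyurea effects were smaller, so noise lowers their r more.

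With hydroxyurea in wild-type cells, 2 miRNAs passed the threshold in the main fit, which ignored the pairing, and 16 with the replicate block. miR-584-5p rose from 27.1 ± 1.5 to 123 ± 35.2 CPM (SD, n = 3), a log2 fold change of 2.19 ± 0.28 (SE; edgeR adjusted p = 0.00296), and miR-129-5p from 39.3 ± 9.96 to 208 ± 58.2 CPM (2.40 ± 0.36, adjusted p = 0.00869), each in 3 of 3 same-numbered pairs. miR-584 lies in an intron of SH3TC2 (chromosome 5, 149062313 to 149062409), and miR-129-5p comes from 2 hairpins. The erythroid miR-144-5p (1.5 ± 0.43, adjusted p = 0.187) and miR-451a (0.65 ± 0.21, adjusted p = 0.246) did not pass over all miRNAs and did adjusted over the list alone. Neither the erythroid (camera adjusted p = 0.865) nor the fetal hemoglobin-linked list (adjusted p = 0.721) passed the set test.

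Thus 2 of 579 miRNAs passed, both higher, while 46 had an unadjusted p under 0.05 (75 with the replicate block) where 28.95 are expected by chance, and the groups did not overlap for 78 (13.5%, against 10% for exchangeable libraries, which these were not). DESeq2 called 11 and limma-voom 2. The count was 0 without WT replicate 1 or WT replicate 3, 1 without WT replicate 2 or WT_HU replicate 2, and 4 without WT_HU replicate 1. With the replicate block 16 passed, 14 higher and 2 lower, among them miR-144-5p (adjusted p = 0.0162), the brain-enriched miR-9-3p (1.32 ± 0.30, unblocked adjusted p = 0.119, blocked 0.0205) and miR-9-5p (blocked 0.0206), miR-3689b-5p (1.35 ± 0.32, 0.119, blocked 0.0407), miR-1246 (1.59 ± 0.38, 0.123, blocked 0.0153), miR-372-3p (blocked 0.0206) and, lower, both arms of the oncogenic miR-21: miR-21-5p (-1.24 ± 0.34, 0.156, blocked 0.0153) and miR-21-3p (-1.47 ± 0.48, 0.264, blocked 0.0206). Further miRNAs named by the rule that did not pass were miR-628-3p (-0.97), miR-628-5p (-0.86) and miR-223-5p (-0.88). The call of miR-584-5p was lost without WT replicate 1 (adjusted p = 0.0532) or WT replicate 3 (0.0561). That of miR-129-5p was lost without WT replicate 1 (adjusted p = 0.102), 2 (0.0842) or 3 (0.0561) or WT_HU replicate 2 (0.0654).

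Of the 26 lists, 4 passed the set test with hydroxyurea in wild type, although 1 miRNA in them passed by itself. The miR-17-92 list lay lower (median -0.26, camera adjusted p = 0.0155, adjusted p = 0.504 with an estimated correlation), with miR-92a-3p at -0.25 and miR-20a-5p at -0.34. The myeloid list lay lower (median -0.40, adjusted p = 0.0155, adjusted p = 0.480 with an estimated correlation), and 2 of its 8 members, both arms of miR-21, were lower adjusted over the list alone. Markers of muscle, liver and neural tissue lay higher (median 0.57, adjusted p = 0.0103, adjusted p = 0.480 with an estimated correlation), with 1 of 14 past the threshold and 4 adjusted over the list alone, namely 3 arms of miR-129 (miR-129-5p, miR-129-1-3p and miR-129-2-3p) and miR-9-3p. With the 2 equal names taken as 1 measurement, 3 of 13 were higher adjusted over the list alone, the median was 0.45 and the list still passed (adjusted p = 0.0186, adjusted p = 0.498 with an estimated correlation). The 2 most abundant of these markers were not rare. Over the 12 libraries miR-1-3p had a mean of 3624 CPM and miR-9-5p of 1948 CPM, and the stromal miR-143-3p had 2411 CPM. Whether such reads came from the K562 cells was not tested. The pluripotency list lay higher (median 1.33, adjusted p = 0.0155, adjusted p = 0.504 with an estimated correlation), with miR-372-3p at 1.33, miR-373-3p at 0.84 and miR-371a-5p at 1.78, of which miR-372-3p and miR-371a-5p were higher adjusted over the list alone. The stromal list, with 1 of 8 higher adjusted over the list alone (miR-199b-5p, 1.36), passed with the replicate block but not without it (adjusted p = 0.0126; 0.0752 without it), and had an adjusted p = 0.683 with the block and an estimated correlation. For the other 21 lists the camera adjusted p lay between 0.106 and 0.875; 2 of 11 erythroid miRNAs and 1 of 9 entries overlapping structural RNA (miR-1246) were higher adjusted over the list alone, and none elsewhere. The 47 most abundant members of the 25 lists with no miRNA past the threshold lay between -1.24 and 1.59 (lowest adjusted p = 0.123), for example miR-486-5p at -0.26, miR-486-3p at -0.24, miR-151a-3p at -0.18 and miR-192-5p at 0.53.

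In knockout cells no miRNA passed the threshold with hydroxyurea, by edgeR (7 with an unadjusted p under 0.05), DESeq2 (0, with 5 unadjusted) or limma-voom (0, with 5 unadjusted). With the replicate block 0 passed too, with 15 unadjusted. All of these lie below the 28.95 expected by chance. The fits by the 3 tools without the block ignored the pairing, so their p-values may be too large here. miR-584-5p was 38.9 ± 2.39 CPM with the drug and 49.3 ± 3.37 CPM without it (-0.34 ± 0.28, SE, n = 3), and miR-21-5p stood at -0.28. The miRNAs named by smallest p, none past the threshold (adjusted p = 0.992 for each), were miR-369-3p (1.23), miR-1257 (0.85), miR-642a-5p (0.51), miR-495-3p (0.86) and miR-3689a-5p (0.49) on the higher side and miR-30a-3p (-0.78), miR-202-5p (-1.09), miR-548h-5p (-0.62), miR-1275 (-1.54) and miR-550b-2-5p (-1.39) on the lower. The groups did not overlap for 21 miRNAs (3.63%, against 10% for exchangeable libraries, which these were not). The 14q32 list lay higher (median 0.13, camera adjusted p = 0.0159, adjusted p = 0.717 with an estimated correlation, and 0.219 over members of at least 10 CPM). The epithelial and the muscle, liver and neural lists passed with the replicate block but not without it (adjusted p = 0.00115 and 0.0133; 0.0782 without it for both), and each had an adjusted p = 0.734 with the block and an estimated correlation. For the other 23 lists the adjusted p lay between 0.0782 and 0.966, erythroid (0.402) and fetal hemoglobin-linked (0.738) included. No member of any of the 26 lists passed, nor did any adjusted over the list alone, and their 49 most abundant members lay between -0.35 and 1.01, with miR-486-3p at -0.18 and miR-151a-3p at -0.35.

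The response to hydroxyurea differed between genotypes for 1 miRNA. The response of miR-584-5p in knockout minus that in wild type was -2.53 ± 0.40 (log2, SE, n = 3 per group; edgeR adjusted p = 0.0185, 0.00664 with the replicate block), in 3 of 3 numbers. With the block, miR-129-5p (-2.29 ± 0.51, unblocked adjusted p = 0.206, blocked 0.00730), miR-1246 (-1.91 ± 0.52, 0.620, blocked 0.0369) and miR-3681-5p (-2.19 ± 0.69, 0.907, blocked 0.0369) passed too, for a count of 4. DESeq2 called 2 and limma-voom 1. In the main fit 18 miRNAs had an unadjusted p under 0.05, and 39 with the block, where 28.95 are expected by chance. The call of miR-584-5p was lost when any library but WT_HU replicate 1 or KO replicate 1 was left out (0 miRNAs passed in those 10 fits and 2 in the other 2), while the difference stayed between -2.74 and -2.19. The adjusted p was 0.214 without WT replicate 1, 0.0980 without WT replicate 2, 0.147 without WT replicate 3, 0.124 without WT_HU replicate 2, 0.103 without WT_HU replicate 3, 0.0800 without KO replicate 2, 0.0961 without KO replicate 3, 0.0656 without KO_HU replicate 1, 0.125 without KO_HU replicate 2 and 0.279 without KO_HU replicate 3.

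Others named, none of which passed, were miR-1298-5p (-2.76) on the lower side and miR-628-3p (1.37), miR-21-5p (0.96), miR-382-5p (1.13), miR-151a-5p (1.04) and miR-495-3p (1.51) on the higher side. In all, 3 lists had a higher response in knockout than in wild type, with no member past the threshold: miR-17-92 (median 0.32, camera adjusted p = 2.81e-04, adjusted p = 0.759 with an estimated correlation; miR-92a-3p 0.09, miR-20a-5p 0.42), 14q32 (median 0.43, 0.0124, adjusted p = 0.759 with an estimated correlation; miR-381-3p 0.43, miR-127-3p 0.05) and myeloid (median 0.38, 0.0373, adjusted p = 0.759 with an estimated correlation; miR-223-3p 0.06). The 14q32 and myeloid calls were lost over members of at least 10 CPM (adjusted p = 0.215 and 0.0517). The miR-183 list passed with the replicate block and not without it, lower in knockout (adjusted p = 0.0330; 0.0923 without it), and had an adjusted p = 0.790 with the block and an estimated correlation. For the other 22 lists the adjusted p lay between 0.211 and 0.997; 1 of 14 markers of muscle, liver and neural tissue (miR-129-5p) and 1 of 9 entries overlapping structural RNA (miR-1246) were lower adjusted over the list alone. The 49 most abundant members of the 26 lists lay between -1.91 and 0.96.

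**Figure D3:**
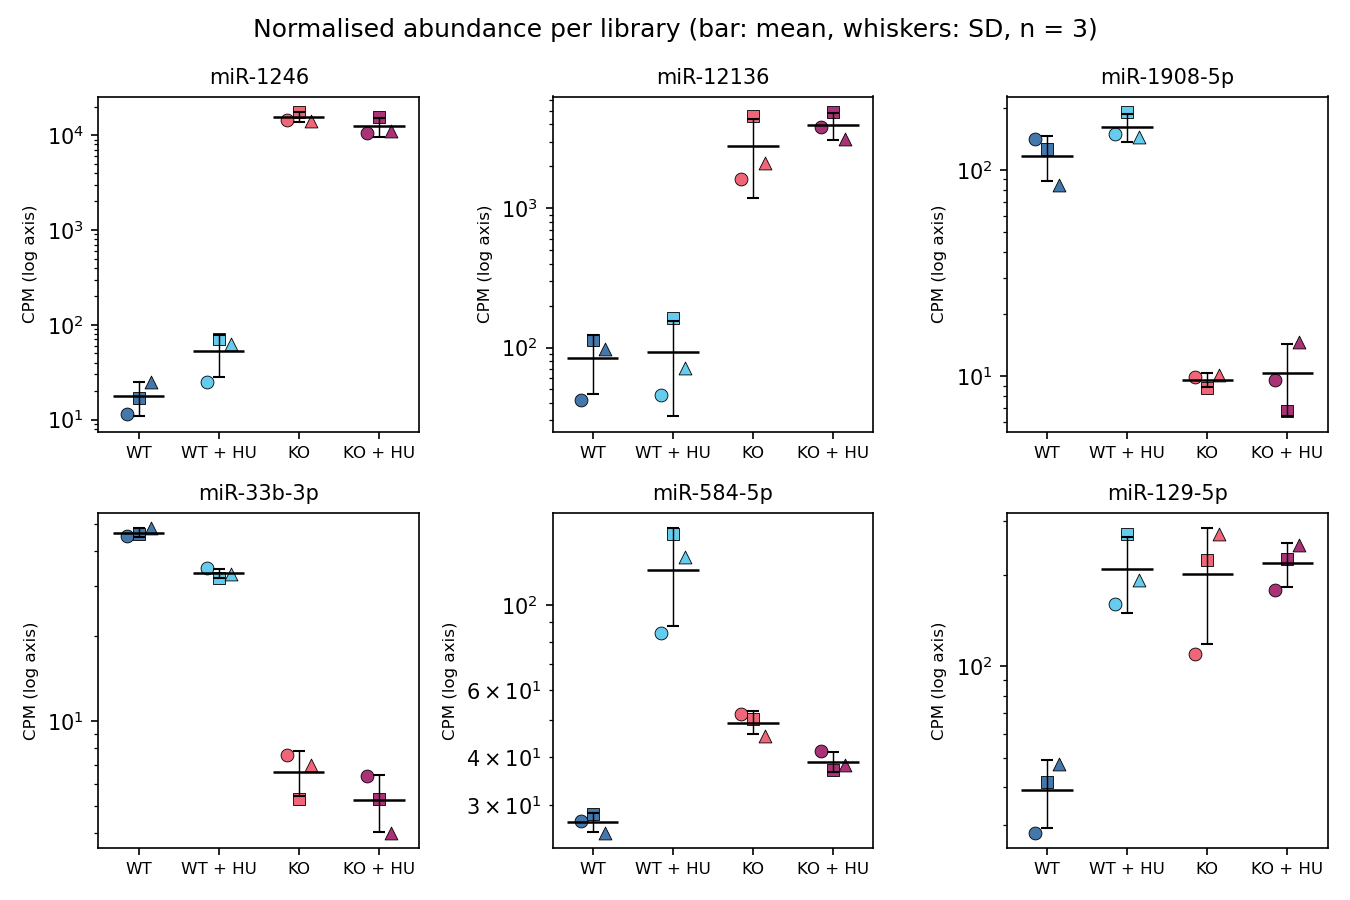
CPM of named miRNAs in each of the 12 libraries on a log axis, by group. Points are libraries and bars give the mean and SD of 3; miR-584-5p lies at 123 CPM in WT_HU and 27.1 CPM in WT, and miR-1246 at 15512 CPM in KO and 17.7 CPM in WT.

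Across the 579 miRNAs, the response to hydroxyurea in wild type and that in knockout correlated with r = 0.141 (Spearman rho = 0.181), and no miRNA passed in both. The median absolute log2 fold change was 0.32 and 0.21 for these responses. For knockout against wild type it was 0.72 untreated and 0.70 under hydroxyurea. Noise lowers a correlation more where changes are small, so this r does not show that the genotypes responded differently. The 2 responses share no library. Both miRNAs that passed with hydroxyurea in wild type also passed as higher in untreated knockout against wild type, where independent lists would share 0.242. Both comparisons use the same WT libraries. Groups simulated without any effect against those libraries, drawn without the pairing by replicate number, shared 0.01 calls on average, with r = 0.492 (0.328 to 0.629 in 100 draws) against an observed r of 0.379, a covariance of 0.195 (0.129 to 0.309) against an observed 0.324, a difference of 0.129, and the same sign for 66.3% of miRNAs against an observed 59.4%. In a simulation added after these values were seen, the groups carried the replicate effects of the block fit and shared 0 calls, with r = 0.473, a covariance of 0.109 (0.0668 to 0.170) and the same sign for 66.3% of miRNAs. With the block in the test as well, the observed overlap was 9 (8 higher and 1 lower in both, where independent lists would share 2.88 and 0.342) against a simulated 0.01, the observed covariance 0.329 against 0.105, and the observed r 0.378 against 0.472. In both simulations no group, knockout included, carried an effect of genotype or drug, so almost no shared calls could arise. The simulated counts of shared calls therefore do not show what shared controls would give beside the real knockout calls. The 3 WT libraries cannot be split into sets of 2, so part of this overlap may come from the shared controls.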

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

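The 3 tests on miR-1246, the GC adjustment and the thinning tests were chosen only after the result was seen, and the depth test at 100 CPM and above only after the share kept among all calls was seen.

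The response to hydroxyurea differed between knockout and wild type for 1 miRNA and 3 lists, each by a test of the difference itself. For miR-584-5p the difference was -2.53 log2 units. The list tests gave adjusted p = 2.81e-04 for the miR-17-92 list, adjusted p = 0.0373 for the myeloid list and adjusted p = 0.0124 for the 14q32 list, and each lost its call with an estimated correlation (adjusted p = 0.759 for all 3).

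For miR-584-5p, 2 technical explanations were considered. If 1 library decided the difference, leaving it out would bring the difference near 0, and the value closest to 0 was -2.19, although the call itself was lost without any library but WT_HU replicate 1 and KO replicate 1 (adjusted p from 0.0656 without KO_HU replicate 1 to 0.279 without KO_HU replicate 3). The within-number value closest to 0 was -1.92, so the difference was not made by 1 replicate number alone. Each number held 1 library of each group, so a batch shared by a number cancels in these values, which therefore do not test batches. Of 100 splits of the 12 libraries, 8 gave at least 1 miRNA past the threshold, so chance cannot be excluded for this count; the highest other count, 17, is several times the real one, and its cause was not tested. The 17 other splits drawn that parted all pairs gave 0 without the block and up to 6 with it, against a real 4, and 7 of the 82 that did not part all pairs gave a call. A difference between the genotypes in the response of miR-584-5p remains a hypothesis found and tested on the same data.

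The rise of miR-1246 and miR-1290 in knockout was weighed against breakdown of structural RNA, batches and depth. The ratio of miR-1246 within replicate numbers was at least 566 in untreated cells and at least 179 under hydroxyurea. The rise was thus not made by 1 number alone. Each number held 1 library of each group, so a batch shared by a number could not make it, and these ratios do not test batches. A difference in handling between knockout and wild-type libraries was not tested. After thinning, the ratio of mean counts was 1035 in untreated cells. Thinning keeps proportions on average, so that ratio could hardly have come out otherwise. Breakdown of structural RNA met the criterion set for it, which was written after the result was seen, only at its limit. The criterion was a minimum share of the other entries above 1 log2 unit. The 8 other tested entries that overlap structural RNA had a median of 1.48 log2 units and 6 lay above 1, the fewest that meet it, with 4 higher past the threshold. Of the 6, miR-664a-3p and miR-664a-5p are arms of 1 hairpin, and miR-1291 (1.13 ± 1.15) and miR-1248 (1.38 ± 0.73) did not pass. Yet miR-1260a (-4.36) and miR-1260b (-2.90) fell and none of the others rose as far as miR-1246, the nearest being miR-12136 (5.04). An effect of SAR1A loss, another difference between the 2 cell populations and breakdown in the knockout samples were confounded with genotype, so the cause could not be told from these data.

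The miRNAs past the threshold in untreated knockout against wild type were weighed against GC content, depth and the splits of the samples. Of the 215 blocked calls with a GC value, 95.3% (205) passed after adjustment for GC content, which argues against a GC trend as their whole cause. After thinning, 79.3% (111 of 140) passed, and the rest cannot be told apart from an effect of depth, because knockout libraries held fewer counts. Among the 56 calls with a mean of at least 100 CPM, 98.2% (55) passed after thinning. Thinning keeps proportions on average and leaves many counts at such levels. These calls could thus hardly be lost, and the share kept says little about depth. The 10 splits of 3 against 3 are too few for a share under 0.05: 1 split, the real one, gave as many as the real 140 calls, and the highest other gave 0.

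For the other comparisons of 3 against 3 the 10 splits were also too few. Under hydroxyurea, 1 split, the real one, gave as many as the real 58 higher and 67 lower (highest other 0), and for hydroxyurea in wild type 1 split gave as many as the real 2 (highest other 0). For hydroxyurea in knockout all 10 splits gave as many as the real 0 by edgeR (highest other 0; 7 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom).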

How the results depend on the processing

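The GC and thinning tests were chosen only after the result was seen; the other alternatives were planned.

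Of 186 results on named miRNAs, 122 passed the threshold and 65 of these passed in every setting run, while 49 of the 64 that had not passed stayed below it in every setting. None of the 122 reversed its direction. Leaving out 1 library ended a call in 194 cases, other settings in 86, and the replicate block in 0, whereas the block brought 13 results on named miRNAs past the threshold, other settings did so in 21 cases and leaving out 1 library in 4. Those 13 are given with their comparisons, and beyond them and the list and count values printed here the block changed no other call on these 186. The cause was not tested unless stated.

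The count for hydroxyurea in wild type was 2, and 11 with DESeq2, 16 with the replicate block, 14 with the block and GC adjustment, and 0 to 4 with 1 library left out. Hydroxyurea in knockout gave 0 with edgeR (7 at an unadjusted p under 0.05, where 28.95 are expected by chance), DESeq2 and limma-voom, and 0 in every other setting. The count for knockout untreated was 140, and 218 with the block, 227 with block and GC adjustment, and 90 to 121 with 1 library left out. Under hydroxyurea 58 miRNAs were higher and 67 lower, and 203 passed with the block and 215 with block and GC adjustment, 85 to 126 with 1 library left out and 89 with only the 2 groups compared. The count for the difference of the responses was 1, and 0 with no filter, 0 after thinning, 2 with DESeq2, 4 with the block, 4 with block and GC adjustment and 0 to 2 with 1 library left out. The call of miR-584-5p ended with no filter (adjusted p = 0.0921) and after thinning (adjusted p = 0.0995). A block uses the pairing of the samples to lower the residual spread, and fits without a library have fewer samples.

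The number of lists past the set test was 4, 1, 4, 2 and 3 for hydroxyurea in wild type, hydroxyurea in knockout, knockout untreated, knockout under hydroxyurea and the difference of the responses. It was 0 with an estimated correlation in all 5, which assigns more spread to a list whose members vary together. With the block it was 3 for hydroxyurea in knockout. Over members of at least 10 CPM it was 0 for hydroxyurea in knockout, 2 for knockout untreated, 1 under hydroxyurea and 1 for the difference, where fewer lists could be tested. The correlation of the 2 hydroxyurea responses, 0.141, was 0.126 with the block, 0.183 with the stricter filter and 0.0937 to 0.117 without a replicate number. The overlap of hydroxyurea in wild type with knockout untreated, 2, was 9 with the block and 1 with the stricter filter. Removing entries that overlap structural RNA moved no library measure by more than 1 SD.

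Some results that had not passed changed sign. With 1 library left out, miR-151a-3p with hydroxyurea in wild type ranged from -0.57 to 0.26. In knockout untreated, miR-200b-3p ranged from -0.41 to 0.61 (and was -0.0163 with only the 2 groups compared), miR-200c-3p from -0.11 to 0.42 and miR-372-3p from -0.75 to 0.64. There miR-33a-3p ranged from -0.73 to 0.30 (-0.0624 with upper quartile factors, -0.0153 with no filter, -0.0282 with the stricter filter, -0.147 with limma-voom, -0.0859 with the block, -0.0839 with block and GC adjustment, -0.0532 with only the 2 groups compared). For the difference of the responses, miR-127-3p ranged from -0.26 to 0.44 (-0.0415 with upper quartile factors, -0.0263 with limma-voom, -0.00582 with the block), miR-223-3p from -0.0866 to 0.40, miR-381-3p from -0.21 to 0.96 and miR-92a-3p from -0.0402 to 0.40. Thinning to 1362273 counts left 111 of the 140 calls in knockout untreated, and 114 calls in all. Of the 56 calls with a mean of at least 100 CPM, 55 stayed.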

Other observations

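The arm comparison below was chosen only after the result was seen, and the 2 hypotheses were prompted by the knockout results while their tests were written before the tested values were seen.

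The 2 arms of a hairpin did not always change together in untreated knockout cells. Of 116 hairpins with both arms tested, 10 had both arms past the threshold, 6 in the same direction and 4 in opposite directions, 35 had 1 arm past it and 71 neither. Opposite arms were those of miR-1307 (1.30 ± 0.35 for 5p and -1.36 ± 0.20 for 3p), miR-130b (-1.82 ± 0.39 and 1.23 ± 0.22), miR-27a (-1.45 ± 0.47 and 0.71 ± 0.20) and miR-330 (1.39 ± 0.27 and -0.89 ± 0.24). The call of miR-1307-5p was lost without WT replicate 1 (adjusted p = 0.122), WT replicate 2 (0.0962), KO replicate 1 (0.0799) or KO replicate 3 (0.0909). Those of the miR-27a arms were also lost without single libraries, as given with the comparison: miR-27a-5p 0.101 without WT replicate 2, 0.0799 without WT replicate 3, 0.130 without KO replicate 1, 0.0525 without KO replicate 2 and 0.0715 without KO replicate 3, and miR-27a-3p 0.108 without WT replicate 1, 0.0636 without WT replicate 2, 0.0646 without KO replicate 1 and 0.0668 without KO replicate 3. Across the 116 hairpins the arms correlated with r = 0.288, and hairpins are not independent replicates. By chromosome, the median log2 fold change was lowest for chromosome 14 (-0.85, 38 miRNAs tested) and chromosome 13 (-0.78, 14 tested) and highest for chromosome 12 (0.77, 13 tested). Chromosome 14 holds the 14q32 cluster (list median -0.93) and chromosome 13 the miR-17-92 cluster. Their medians may thus reflect those clusters, and a shift of a whole chromosome was not tested.

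One hypothesis was that the knockout cells held fewer copies of the long arm of chromosome 10 beyond SAR1A (chromosome 10, 70147289 to 70170514), prompted by the lower miR-146b-3p and miR-1307-3p. The arms of those 2 hairpins were left out. The other 11 tested miRNAs beyond SAR1A had a median of 0.44 log2 units, which was exceeded by 15.6% of 10000 random sets, with 1 higher and 0 lower past the edgeR threshold. Fewer copies would have lowered them together, so this was not found.

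A second hypothesis was lower output of sterol-responsive host genes, prompted by miR-33b-3p of SREBF1 and miR-1908-5p of FADS1. Besides those, 2 miRNAs of such hosts were tested, miR-1908-3p of FADS1 (-2.40 ± 0.63; adjusted p = 0.0573 without KO replicate 1) and miR-33a-3p of SREBF2 (0.07 ± 0.72, a sign that changed with the processing), with a median of -1.16. miR-1908-3p comes from the same hairpin as miR-1908-5p, so 1 independent host remained, which is too few to decide.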
